A study of Mus musculus with 69 samples.

How the data were processed

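Total RNA libraries of mouse medial prefrontal cortex, 69 in number, were analysed, 30 from controls and 39 from carriers of KCNH2-3.1, at 2, 6, 10 and 22 weeks of age. Per the labels' protocols, libraries were made after ribosomal RNA depletion with a stranded total RNA kit and sequenced as paired ends on a HiSeq 2000. Reads were aligned with TopHat2 2.0.9 to mm10, per the submitters' processing notes, and the deposited values are raw counts per gene made with featureCounts 1.4.3-p1, per the file headers. Per the file headers the counts are of single reads, reverse-stranded, over exons and summed by gene, with an Ensembl annotation of GRCm38 with spike-in sequences added. Each file held 46609 features, 46517 Ensembl genes and 92 ERCC spike-in sequences, and 46005 of the genes matched a symbol. Separate animals for each library are not given in the sources used here beyond 1 label per library, and replicate numbers here follow only the order of the samples.

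Spike-in features were left out of library sizes and tests. They made up 4.13% to 22.43% of counts in the 12 libraries of the CTX title series and at most 2 reads in any other library. Total counts, in units of 1e6 reads, had a median of 37.6 and ran from 8.09 to 135.007. CPM, counts scaled to 1e6 reads, were computed here from the deposited counts with TMM library sizes, and log2 CPM with a prior count of 2. Markers of other tissues and the check of sex used counts per 1e6 reads of plain total count. Within groups, 280 pairs of libraries were checked for duplicates, with a lowest chi-squared per gene of 4.05 and no identical pair. Sex given in the labels was checked by whether Xist exceeded the Y-linked Ddx3y, with 0 mismatches, a check that a mixture could pass. Among males Xist was 7.409 in control_6wk replicate 5 and 6.793, 1.286 and 0.812 in KCNH2-3.1_10wk replicates 1, 6 and 7. Other males had at most 0.552.

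Genes were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), with TMM normalization, filterByExpr, robust quasi-likelihood F tests and Benjamini-Hochberg adjustment over the 18704 genes that passed the filter. A gene was called at an adjusted p under 0.05 with no fold threshold. A single fit of all 69 libraries held title series nested within age, a genotype effect at each age and sex, in 13 columns with 56 residual degrees of freedom, and the common biological coefficient of variation was 0.154. Genotypes were compared at each age, as an equal-weight average over the ages, and by a test that the 4 effects were equal. Ages were compared at the control level, 2 with 6 weeks between the P14 and D series, 6 with 10 weeks within D and 6 with 22 weeks within CTX. The D and CTX series share 1 genotype effect at 6 weeks, so the fitted 6-week control level of each also draws on its transgenics. Errors of log2 fold changes (SE) were derived as the absolute log2 fold change divided by the square root of its F statistic. Errors of CPM are standard deviations between libraries (SD).

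Gene lists were tested with limma camera at a preset correlation of 0.01 between genes, adjusted over 39 lists within a contrast, and again with the correlation estimated for each list. The lists covered complement components, complement receptors and regulators, cell types of the brain and its coverings, blood, synapses, ion channels, development, stress and hormone responses, metabolism, and genes at the insertion site of a transactivator driver. Counts of list members adjusted over the list alone are given beside those over all genes. The lists, the model, the gene-naming rule and most alternatives were fixed before the data were examined.

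Genes named in the text follow a rule. Kcnh2 was always named. Of genes past the threshold with a mean of at least 1 CPM and a proper symbol, the rule takes the 5 largest rises, the 5 largest falls, and the 5 of smallest p in each direction. Where fewer than 5 passed in a direction, those of smallest p filled it up to 3, and are given with no word of change. For each list up to 4 members of smallest p were eligible where the list or a member passed, 4 always for complement lists, with C4b, C3, C1qa, C1qb and C1qc always and the 5 driver-site genes always, and for the test of equal effects the 5 of smallest p. This gave 433 distinct genes, of which the text prints a part. Some genes that the rule takes are not reported here.

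The test was run first on simulated counts drawn from the means and library sizes of these libraries. At a log2 fold change of 0.5, 1 and 2 it recovered 73.7%, 85.0% and 100% of changed genes at 2 weeks, 37.5%, 76.5% and 87.5% at 6 weeks, 32.1%, 73.7% and 100% at 10 weeks, and 27.8%, 64.7% and 78.9% at 22 weeks, with 1, 3, 6 and 3 unchanged genes called. At 0.5 the shares rest on 19, 16, 28 and 18 changed genes at 2, 6, 10 and 22 weeks. In a simulated change of 0.5 of the interferon-response list at 10 weeks, the changed list was called and 0 of the others were. The genes of that list are part of the 10-week set, so the ages are not compared on like gene sets. The simulated genes varied independently of one another. These runs therefore do not test false calls where genes or libraries vary together.

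Alternatives were RLE size factors, no low-count filter, a filter of 1 CPM in 10 libraries, DESeq2 1.42.0, no title series, males only, 2 surrogate variables (sva 3.50.0), each age fitted alone and each library left out in turn. Added after the data had been seen were fits of the 6-week D and CTX series apart, a fit without the 6-week D controls and title series, an average and a test over 2, 10 and 22 weeks, age contrasts at the transgenic level, age contrasts with a 6-week genotype effect of its own in each series, and lists without control_22wk replicate 1. Values for the D or CTX series alone are separate genotype effects in 1 fit of all 69 libraries, which share its spread. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The series title names complement, and the human transgene was not analysed here because no feature counts it.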

Results

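RNA of the medial prefrontal cortex was sequenced from mice carrying KCNH2-3.1 and from control mice at 2, 6, 10 and 22 weeks of age. KCNH2-3.1 is a brain-expressed primate isoform of KCNH2, the gene of the hERG1 (Kv11.1) voltage-gated potassium channel. The comparison asked which transcripts of this cortical region differed with the transgene at each age, and the series title names complement. At 2 weeks there were 7 control and 10 transgenic libraries, at 6 weeks 9 and 9, at 10 weeks 10 and 11, and at 22 weeks 4 and 9. Males gave 65 of the 69 libraries and females gave 4. Total counts, in units of 1e6 reads, ran from 8.09 to 135.007 per library, with medians of 91.8 at 2 weeks, 60.03 at 6 weeks, 20.996 at 10 weeks and 28.9 at 22 weeks. The sample titles fell into 4 naming series. At 2 weeks all titles began with P14, and at the later ages they were bare numbers (controls only), a number with CTX, or D with a number. At 6 weeks the controls were 2 number, 2 CTX and 5 D libraries and the transgenics 2 CTX and 7 D libraries. At 10 weeks 3 controls had number titles, and the other 7 controls and all 11 transgenics had D titles. At 22 weeks all 4 controls had CTX titles, against 4 CTX and 5 D transgenics. Genotypes were therefore compared within title series. The number controls and the 22-week D transgenics have no libraries of the other genotype in their series and age. They therefore inform the spread and not the genotype effects.

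Kcnh2 (ENSMUSG00000038319), the mouse gene of the channel, was detected in every library and its level did not differ between genotypes at any age by the test used. At 2 weeks Kcnh2 averaged 10.99 ± 2.05 CPM in controls (SD, n = 7) and 9.79 ± 1.10 CPM in transgenics (SD, n = 10). At 6 weeks the means were 17.02 ± 4.20 (n = 9) and 14.9 ± 2.17 CPM (n = 9). They were 19.3 ± 3.13 (n = 10) and 17.6 ± 3.15 CPM (n = 11) at 10 weeks, and 12.9 ± 1.72 (n = 4) and 17.2 ± 6.77 CPM (n = 9) at 22 weeks. The fitted log2 fold changes of Kcnh2 were -0.17 ± 0.10 (SE) at 2 weeks, -0.11 ± 0.11 at 6 weeks, -0.072 ± 0.11 at 10 weeks and -0.28 ± 0.17 at 22 weeks. Averaged over the ages Kcnh2 had -0.15 ± 0.063 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.418 for the average). In the 22-week transgenics Kcnh2 was 22.4 ± 3.66 CPM in the 5 D libraries and 10.6 ± 1.246 CPM in the 4 CTX libraries, and the 22-week log2 fold change was 0.43 when title series was left out of the model. The 46609 counted features held mouse genes and spike-in sequences and no feature for the human transgene, so Kcnh2 does not check the genotype labels. Kcnh2 lies on chromosome 5 from 24319589 to 24351604 (GRCm38).

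**Figure D1:**
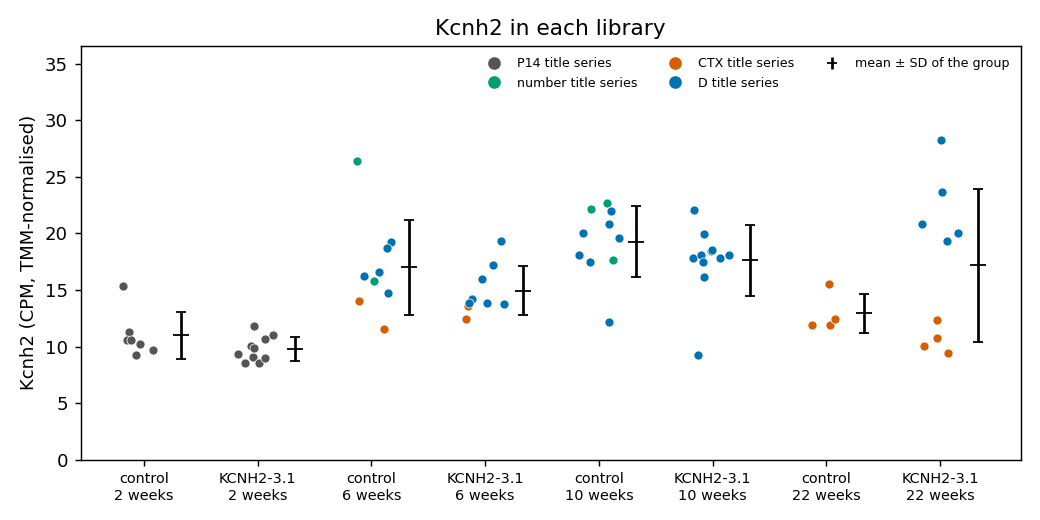
Kcnh2 in CPM on the vertical axis for each of the 69 libraries, grouped along the horizontal axis by age and genotype, with the mark giving the title series and the bars the mean and SD of each group. Group means ran from 9.79 CPM in the 2-week transgenics to 19.3 CPM in the 10-week controls, and the genotypes overlapped at every age.

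At 2 weeks no gene differed between genotypes, and of the cell type lists only microglial markers were called with an estimated correlation. Microglial markers were lower in the transgenics, with 19 of 20 measured members negative and a median log2 fold change of -0.12 (adjusted p = 0.0122 with an estimated correlation). Among them were the lipid-sensing receptor Trem2 (-0.25 ± 0.090, from 5.42 ± 0.225 CPM, n = 7, to 4.57 ± 0.472 CPM, n = 10), the growth factor receptor Csf1r (-0.16 ± 0.072), the lysosomal protein Cd68 (-0.24 ± 0.11) and Olfml3 (-0.21 ± 0.085). Markers of striatal projection neurons were higher as a list (median 0.40, 14 of 15 positive), a call lost at adjusted p = 0.510 with an estimated correlation, with values of 0.47 ± 0.18 for the phosphodiesterase Pde10a, 1.003 ± 0.46 for the adenosine receptor Adora2a and 1.16 ± 0.55 for the dopamine receptor Drd2. KCNH2-3.1_2wk replicate 2 had a striatal marker score of 4.16 in mean log2 CPM against at most 3.02 in the other 9 transgenics. Markers of meningeal fibroblasts (median -0.33, all 12 members negative), of myelinating oligodendrocytes (-0.21, 17 of 18) and of olfactory bulb neuroblasts (-0.22, 11 of 12) were lower as lists, and all 3 calls were lost at adjusted p = 0.510 with an estimated correlation.

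By camera with Benjamini-Hochberg adjustment over 39 lists, the adjusted p was 3.20e-12 for microglia. It was 5.36e-08 for striatal neurons, 2.03e-06 for myelinating oligodendrocytes, 7.14e-05 for neuroblasts and 8.57e-04 for meningeal fibroblasts. Endothelial cells and pericytes (3.63e-04), astrocytes (0.00825), interferon response (0.00825), oligodendrocyte precursors (0.0140) and MHC class I (0.0278) were lower and postsynaptic glutamate genes (0.0173) higher, and each of these calls was lost at adjusted p = 0.510 with an estimated correlation. Immediate early genes were lower at 0.00825, with adjusted p = 0.549 with an estimated correlation. Without title series reactive astrocytes were also called, lower (0.0431). No member of these lists passed over all genes or when adjusted over the list alone. Of single genes, edgeR's quasi-likelihood test called 0 of 18704 at an adjusted p under 0.05, with 151 at an unadjusted p under 0.05, and DESeq2 called 1. The genes of smallest p included the tetraspanin Cd82 (-0.51 ± 0.13), the complement receptor C3ar1 (-0.51 ± 0.15), Crot (-0.35 ± 0.11), Fam171b (0.22 ± 0.061), the mitochondrial import chaperone Timm10 (0.28 ± 0.080) and the protocadherin Pcdha12 (0.43 ± 0.12), none of which passed.

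At 6 weeks 133 genes were lower and 51 were higher in the transgenics. Depp1, a FOXO target that modulates autophagy, fell to 0.0734 of the fitted control level (log2 fold change -3.77 ± 0.35), and Tmem252, a transmembrane protein gene, to 0.108 (-3.22 ± 0.30). Both falls rested largely on high values in the D controls. In the number and CTX controls Depp1 lay near the D transgenics, and Tmem252 between the D transgenics and D controls, as given below. The transcription factor genes Maff (-2.39 ± 0.32) and Atf3 (-1.99 ± 0.43) fell. The endothelial early gene Apold1 (-1.95 ± 0.27) fell too, as did the vasoconstrictor peptide gene Edn1 (-1.92 ± 0.22), the NF-kappaB inhibitor Nfkbia (-1.11 ± 0.12) and the kinase anchor Akap12 (-1.17 ± 0.12). The rises of smallest p were 0.57 ± 0.093 for the tight-junction gene Ocln, 0.54 ± 0.092 for the RNA-binding protein gene Mex3b and 0.58 ± 0.10 for the iron exporter Slc40a1. Rises followed of 0.31 ± 0.061 for the zinc exporter Slc30a1 and 0.44 ± 0.089 for the cap methyltransferase Cmtr2. In the CTX series alone Maff (0.567), Atf3 (0.810), Apold1 (0.011), Akap12 (0.093), Mex3b (-0.017) and Slc40a1 (-0.146) turned direction. With both the D controls and title series left out Maff (0.305), Atf3 (0.384), Apold1 (0.287), Akap12 (0.078), Edn1 (0.125), Rassf9 (-0.032), Mex3b (-0.089), Slc40a1 (-0.153), Slc30a1 (-0.055) and Cmtr2 (-0.066) did. No gene named at 6 weeks passed in either of these fits, which were chosen after the data had been seen. The largest rises were in the receptor genes Vmn1r58 (2.06 ± 0.47) and Olfr613 (1.83 ± 0.47), and in Rassf9 (0.94 ± 0.24), Mycn (0.91 ± 0.22) and the Y RNA gene Rny3 (0.90 ± 0.24). Without KCNH2-3.1_6wk replicate 1, the library of fewest counts, 30 of the 51 higher genes and 120 of the 133 lower genes stayed called, and Vmn1r58 (0.327), Olfr613 (0.401) and Rny3 (0.847) did not pass. In that library the most counted gene was Gm26917, with 12.518% of counts. Mitochondrial reads made up 3.43% of its counts, and at least 5.455% in the other 6-week libraries.

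By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 8.06e-12 for Depp1, 1.83e-10 for Nfkbia, 2.32e-09 for Edn1 and 3.34e-05 for Ocln, and 0.0332 for Olfr613. Of the 184 genes, 58 changed more than 2-fold, 18 up and 40 down. The 5 D controls stood apart from all other 6-week libraries for the lower genes. Depp1 was 9.71 ± 0.809 CPM in the D controls (range 8.69 to 10.9), 0.820 ± 0.0143 CPM in the 2 number controls, 0.626 ± 0.0735 CPM in the 2 CTX controls and 0.564 ± 0.294 CPM in the 7 D transgenics (range 0.401 to 1.22). Tmem252 was 7.33 ± 0.654 CPM in the D controls, 1.57 ± 0.219 and 2.08 ± 0.542 CPM in the number and CTX controls, and 0.669 ± 0.225 and 0.572 ± 0.232 CPM in the D and CTX transgenics. Mex3b, which rose, was 11.9 ± 0.674 CPM in the D controls against 21.5 ± 0.845 CPM in the number controls and 20.02 ± 5.80 CPM in the D transgenics. With a genotype effect of its own for each series in the fit of all 69 libraries, edgeR called 365 genes in D and 0 in the 4 CTX libraries. With the D controls left out and no title series in the model 15 genes were called, 1 of them among the 184. Differences between series enter this last fit.

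**Figure D2:**
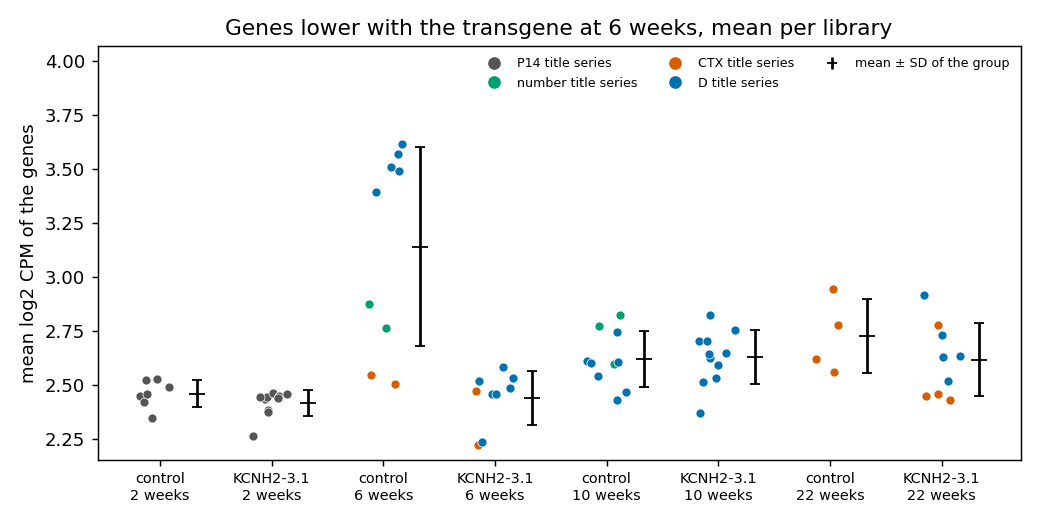
Mean log2 CPM of the 133 genes lower with the transgene at 6 weeks, on the vertical axis, for each of the 69 libraries grouped by age and genotype, with the mark giving the title series. The 5 D controls of 6 weeks lay between 3.39 and 3.62, and the other 6-week libraries between 2.22 and 2.88. The 133 genes were chosen by a test on these same libraries.

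Of the fixed lists, glucocorticoid response held the most genes that fell at 6 weeks, 7 of the 133. All 13 glucocorticoid-response genes were negative, and 7 fell over all genes and 12 when adjusted over the list alone. They included the serum and glucocorticoid kinase Sgk1 (-1.06 ± 0.13, 122 ± 18.7 CPM in D controls and 48.9 ± 9.12 in D transgenics), the EGFR inhibitor Errfi1 (-0.73 ± 0.097), the glucocorticoid receptor co-chaperone Fkbp5 (-0.45 ± 0.090) and the transcription factor Cebpd (-1.54 ± 0.31). Of 18 immediate early genes 3 fell (7 over the list alone), namely Fosl2 (-0.53 ± 0.13), Nr4a1 (-0.79 ± 0.20) and Dusp1 (-0.61 ± 0.17). Of 11 heat-shock genes 4 fell (4 over the list alone), the chaperones Hspa1a (-0.68 ± 0.14), Hspa1b (-0.70 ± 0.18), Hspb1 (-0.82 ± 0.20) and Dnajb1 (-0.32 ± 0.078). Of 12 reactive-astrocyte genes 2 fell (5 over the list alone), the iron-binding lipocalin Lcn2 (-4.82 ± 0.95) and again Hspb1. The glucose transporter Slc2a1 (-0.77 ± 0.10) and the pericyte potassium channel Kcnj8 (-0.51 ± 0.12) fell among 15 vascular markers (2 lower and 1 higher over the list alone). So did the antigen-presentation gene Cd74 (-1.02 ± 0.27) among 12 activated-microglia genes (3 over the list alone). The clock gene Arntl (-0.28 ± 0.069) fell among 14 circadian genes (2 lower and 1 higher over the list alone). The purinergic receptor P2ry13 rose among 20 microglial markers (0.52 ± 0.11; 3 higher and 2 lower over the list alone). Without KCNH2-3.1_6wk replicate 1 Fosl2 (-0.483), Dusp1 (-0.602) and Dnajb1 (-0.262) did not pass.

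The camera adjusted p was 3.80e-25 for glucocorticoid response (3.34e-06 as adjusted p with an estimated correlation) and 2.50e-12 for immediate early genes (adjusted p = 0.0334 with an estimated correlation). It was 1.05e-06 for heat shock and 2.10e-05 for reactive astrocytes (adjusted p = 0.0199 with an estimated correlation for both). Meningeal fibroblast markers fell as a list with a median of -0.77 (2.75e-09, adjusted p = 0.199 with an estimated correlation) and no single member passed (3 over the list alone), with -1.12 ± 0.42 for the collagen gene Col1a1. The unfolded protein response (0.0220, adjusted p = 0.688 with an estimated correlation; 0 members passed, 1 over the list alone) and activated microglia (0.0295, adjusted p = 0.633 with an estimated correlation) were called with the preset correlation only. For the CTX effect fitted apart the immediate early list was higher in the transgenics (camera adjusted p = 0.00536) and none of the other 6 lists was called. Called lower there, and not in the main fit, were MHC class I (1.83e-07), interferon response (6.06e-07), vascular (0.0216), upper-layer (0.0225), striatal (0.0298) and microglial (0.0345) lists. With both the D controls and title series left out 4 of the 7 lists kept their call, the glucocorticoid (0.552) and heat-shock (0.706) lists were not called and the unfolded protein list was higher (0.00473). A further 12 lists were then called lower, from myelin (8.92e-07) and astrocytes (1.02e-05) to dopamine signalling (0.0311), with microglia at 1.87e-05. That fit sets 7 D and 2 CTX transgenics against 2 number and 2 CTX controls, so differences between series enter it. With title series alone left out 6 of the 7 lists kept their call and the unfolded protein list did not (0.744). Blood (0.00469), MHC class I (0.0161) and vascular (0.0279) lists were then also called lower. For the D effect fitted apart activated microglia was not called (0.0569). The fits by series and the fit without the D controls and title series were chosen after the data had been seen.

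C1qa at 6 weeks was the only complement transcript that passed, and errors of the others were often wide, most of all at 22 weeks. C1qa, a chain of the initiating C1q complex, fell at 6 weeks from 37.8 ± 5.05 CPM in controls (n = 9) to 31.9 ± 4.75 CPM in transgenics (n = 9; log2 fold change -0.29 ± 0.071). It was 38.04 ± 4.64 against 29.9 ± 2.66 CPM in the D libraries and 42.2 ± 5.67 against 39.00 ± 3.15 CPM in the CTX libraries, and 32.99 ± 0.887 CPM in the 2 number controls. Its values at the other ages were -0.14 ± 0.069 at 2 weeks, -0.002 ± 0.070 at 10 weeks and -0.23 ± 0.10 at 22 weeks. The sister chains C1qb (-0.077 ± 0.12) and C1qc (-0.005 ± 0.15) did not pass at 6 weeks, nor did the opsonin precursors C4b (-0.16 ± 0.24) and C3 (0.079 ± 0.41). Their wider errors do not set these genes apart from C1qa, and no test compared them with it. At 10 weeks C3 had a log2 fold change of -1.06 ± 0.48, from a level of 0.269 ± 0.152 CPM in controls. Among regulators and receptors, the C1 inhibitor Serping1 had -0.55 ± 0.27, -0.91 ± 0.30, -0.68 ± 0.29 and -0.65 ± 0.17 at 2, 6 and 10 weeks and averaged, and the anaphylatoxin receptor C3ar1 -0.51 ± 0.15 at 2 weeks.

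For C1qa the adjusted p was 0.0177 at 6 weeks and 0.0537 averaged over the ages by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 15 measured complement components 1 fell at 6 weeks, and 1 when adjusted over the list alone, and the list's camera adjusted p was 0.273. Of 22 receptors and regulators 0 passed over all genes and 0 over the list alone (0.0734). The receptors and regulators were called lower at 6 weeks without title series (0.0121) and with the D controls also left out (0.0311), and at 10 weeks without title series (0.0459). Both lists were lower in the average over the ages. The components were lower at 0.0323 (median -0.091, 2 of 15 over the list alone, adjusted p = 0.220 with an estimated correlation). The receptors and regulators were lower at 0.00112 (median -0.063, 3 of 22 over the list alone, adjusted p = 0.0222 with an estimated correlation). No member of either list passed over all genes in the average. At 2 weeks the receptors and regulators were lower (0.00825, 1 of 22 over the list alone, adjusted p = 0.151 with an estimated correlation) and the components were not called (0.103). At 10 weeks the 2 lists had camera adjusted p values of 0.449 and 0.276, and at 22 weeks of 0.426 and 0.120, where the components had a median of 0.027 and a mean of -0.34. The series title names complement, so the choice of these 2 lists and their counts are not independent of it.

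**Figure D3:**
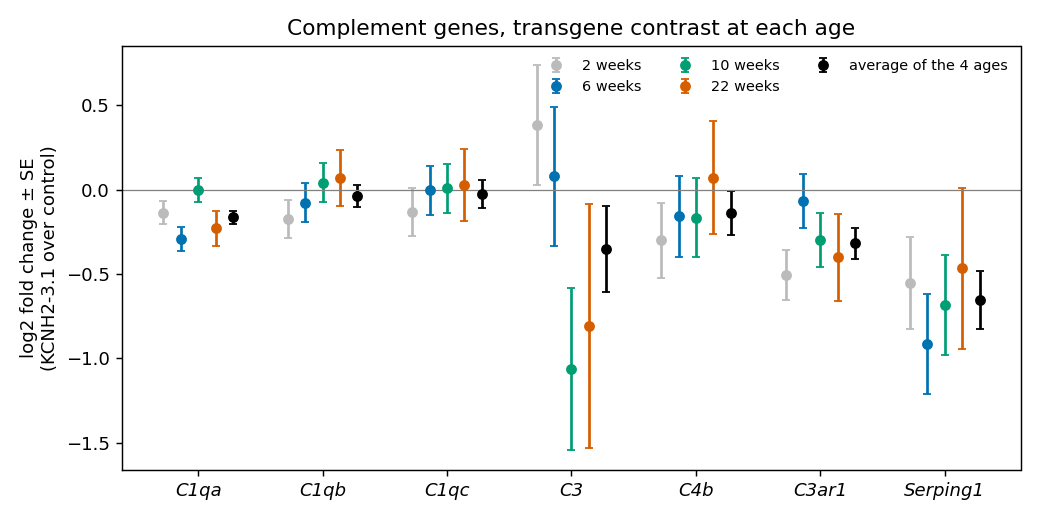
Fitted log2 fold change of transgenic over control libraries, with its SE, on the vertical axis for complement genes along the horizontal axis. Colours give the 4 ages and their average. C1qa at 6 weeks (-0.29 ± 0.071) is the only one of the plotted values that passed an adjusted p of 0.05.

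At 10 weeks no single gene differed between genotypes, and the 4 lists that were called lost their calls with an estimated correlation. All 30 cytosolic ribosomal protein genes were positive (adjusted p = 0.567 with an estimated correlation), with a median of 0.098 and examples of 0.18 ± 0.070 for Rpl27 and 0.15 ± 0.063 for Rps15. All 24 nuclear respiratory-chain genes were positive (adjusted p = 0.722 with an estimated correlation), with a median of 0.080, including the complex I gene Ndufb9 (0.14 ± 0.064) and the cytochrome oxidase gene Cox4i1 (0.098 ± 0.057). Meningeal fibroblast markers were lower (median -0.60, adjusted p = 0.722 with an estimated correlation), with -1.02 ± 0.51 for the proteoglycan Ogn and -0.86 ± 0.37 for the anion transporter Slc22a6. Microglial markers were lower (median -0.088, adjusted p = 0.699 with an estimated correlation), with -0.15 ± 0.074 for Siglech. The splicing factor Cwc22 had -1.75 ± 0.40, the sulphate transporter Slc26a2 -0.43 ± 0.090, the lysozyme Lyz2 -0.68 ± 0.17, Timm10 0.37 ± 0.085 and Fam171b 0.26 ± 0.060.

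None of these genes passed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.162 for Cwc22 and 0.108 for Slc26a2). EdgeR called 0 of 18704 genes, with 678 at an unadjusted p under 0.05, and DESeq2 called 4. At the preset correlation the camera adjusted p was 3.42e-17 for ribosomal protein genes, 3.62e-06 for the respiratory chain, 3.49e-05 for meningeal fibroblasts and 0.00124 for microglia. No member of the 4 lists passed over all genes or when adjusted over the list alone. Without title series deep-layer markers were called higher (0.0134).

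At 22 weeks 21 genes were lower and 7 higher in the transgenics. With title series in the model, the genotype effect of this age came from the 4 CTX controls and 4 CTX transgenics. The 5 D transgenics entered only the spread. The largest falls were in the pituitary hormone genes Gh (growth hormone, -10.30 ± 1.69), Prl (prolactin, -9.66 ± 1.63) and Pomc (pro-opiomelanocortin, -5.33 ± 0.82), all of which rested on a single control. In control_22wk replicate 1 Gh was 7513 CPM against at most 4.589 CPM in any other library, Prl 1179 against 1.184 CPM and Pomc 153.8 against 1.491 CPM. Igsf1, a pituitary membrane glycoprotein gene, had -2.33 ± 0.53, and the secretory GTPase gene Rab27a -1.15 ± 0.27. Smaller falls were in the cargo receptor Surf4 -0.39 ± 0.072 (51.8 ± 3.999 CPM in the 4 CTX controls and 39.5 ± 5.74 CPM in the 4 CTX transgenics) and the serine carboxypeptidase Scpep1 -0.55 ± 0.12. Rises were of 1.27-fold to 1.48-fold among the 6 named genes, in Mex3b (0.57 ± 0.13), the thyroid hormone-activating deiodinase Dio2 (0.45 ± 0.095, 188 ± 25.6 to 258 ± 49.9 CPM within CTX) and the mitochondrial transport adaptor Trak2 (0.39 ± 0.078, 229 ± 27.5 to 300.6 ± 39.97 CPM). The others were Mfap3l (0.38 ± 0.085), the junction protein gene Pkp4 (0.35 ± 0.076) and the G protein subunit Gna13 (0.34 ± 0.078). In the 5 D transgenics, which have no D control of that age, Dio2 was 115 ± 5.99 CPM and Trak2 189 ± 4.08 CPM, below the CTX controls.

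By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 3.66e-04 for Pomc, 0.00144 for Gh, 0.00324 for Surf4, 0.0125 for Trak2 and 0.0389 for Mex3b. Without control_22wk replicate 1 edgeR called 1 gene, Unc45b (log2 fold change 7.75, adjusted p = 0.00431 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), which is named after its value was seen, and with the 22-week libraries fitted alone it called 0. Of the lists called at 22 weeks, mitochondrially encoded genes were higher (median 0.54, all 13 positive, mt-Co1 0.56 ± 0.16), as were astrocyte markers (median 0.14, all 15 positive, the glutamate transporter Slc1a2 0.34 ± 0.13), ribosomal protein genes (median 0.092) and upper-layer markers (median 0.14, Rorb 0.42 ± 0.14). These calls were lost at adjusted p = 0.381, 0.442, 0.726 and 0.442 with an estimated correlation, in this order. Unfolded protein response genes (median -0.20, the chaperone Calr -0.35 ± 0.096), heat-shock genes (median -0.15, Hspa8 -0.27 ± 0.083), olfactory bulb neuroblast markers (median -1.11, Dlx5 -0.90 ± 0.39) and blood markers (median -0.71, the globin Hba-a1 -1.10 ± 0.39) were lower, and lost their calls at adjusted p = 0.262, 0.262, 0.726 and 0.569 with an estimated correlation, in this order.

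The 22-week lists passed camera at 4.09e-07 (mitochondrial), 2.14e-06 (unfolded protein response), 1.45e-04 (astrocyte), 4.25e-04 (heat shock), 5.47e-04 (ribosomal), 0.0150 (neuroblast), 0.0252 (upper layer) and 0.0413 (blood). No member passed over all genes, and adjusted over the list alone 2 mitochondrial, 1 ribosomal and 1 upper-layer gene were higher and 2 unfolded protein response, 2 heat-shock and 1 blood gene lower. Reads of the mitochondrial chromosome made up 31.8% to 43.6% of counts in the CTX transgenics, 21.8% to 32.7% in the CTX controls and 5.23% to 22.0% in the D transgenics. Without title series in the model, differences between D and CTX libraries enter the contrast, and the ribosomal list was lower (camera adjusted p = 2.2e-09). The astrocyte (0.772), neuroblast (0.358), heat-shock (0.196), blood and unfolded protein (both 0.179) and mitochondrial (0.121) lists were then not called. Newly called without title series were the potassium channel (1.39e-04), presynaptic (0.00421), postsynaptic (0.0256) and axon guidance (0.0259) lists, higher, and the respiratory-chain (1.24e-06) and myelin (0.0415) lists, lower. With RLE size factors reactive astrocytes were called, lower (0.0427). Without control_22wk replicate 1 the ribosomal (0.432) and neuroblast (0.0627) lists were not called, and microglia was called, lower (0.0387, against 0.0600 with it).

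Averaged over the 4 ages with equal weight, 19 genes were lower and 5 higher in the transgenics. The 22-week part of the average came from the CTX libraries alone. The falls included the chaperone Hspb1 (-0.56 ± 0.12), Nfkbia (-0.40 ± 0.065), the thioredoxin inhibitor Txnip (-0.41 ± 0.073), Cd82 (-0.43 ± 0.078), Akap12 (-0.35 ± 0.068) and the actin-binding Cnn2 (-0.41 ± 0.082). Also lower were the ephrin receptor Epha2 (-0.57 ± 0.13), the glucocorticoid-induced Rasd1 (-0.57 ± 0.11) and Crispld2 (-0.69 ± 0.16), Tmem252 (-0.76 ± 0.17) and Sgk1 (-0.33 ± 0.073). The rises included the integrin subunit gene Itga4 (0.33 ± 0.076), Mex3b (0.25 ± 0.050), Mfap3l (0.16 ± 0.033) and Fam171b (0.15 ± 0.034). Itga4 and Fam171b belong to the cluster around Cwc22 on chromosome 2 that is described below. Cd82 was 4.75 ± 0.526 CPM in 2-week controls and 3.36 ± 0.576 CPM in 2-week transgenics, and 11.3 ± 2.70 and 8.11 ± 2.02 CPM at 6 weeks. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.00113 for Nfkbia, 0.00428 for Cd82, 0.0146 for Mex3b and 0.0445 for Itga4. In the average over 2, 10 and 22 weeks, an alternative chosen after the data had been seen, edgeR called 0 genes, and without control_22wk replicate 1 it called 6.

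Of the lists, glucocorticoid response (7.42e-07), heat shock (1.10e-06) and reactive astrocytes (3.60e-05) were lower in the average, at adjusted p = 0.0222 with an estimated correlation for each. In these lists 1 of 13, 1 of 11 and 1 of 12 members fell, and 6, 4 and 2 over the list alone. At 2, 6, 10 and 22 weeks the medians were -0.078, -0.49, 0.15 and -0.18 for glucocorticoid response, with 10 of 13 members positive at 10 weeks. They were -0.030, -0.084, 0.002 and -0.15 for heat shock and -0.086, -0.26, -0.028 and -0.20 for reactive astrocytes. The 6-week values entering this average include the D controls, which stood apart for the genes lower at that age. Microglial markers were lower by a median of -0.088 (6.92e-06, adjusted p = 0.111 with an estimated correlation), with -0.22 ± 0.059 for Laptm5 and -0.12 ± 0.042 for Csf1r, and 7 of 20 members passed when adjusted over the list alone and 0 over all genes. Meningeal fibroblasts (6.92e-06, adjusted p = 0.249 with an estimated correlation) and unfolded protein response (6.92e-06, adjusted p = 0.118 with an estimated correlation) were lower. Immediate early genes (1.83e-05), activated microglia (0.00156) and MHC class I (0.00427) were lower and mitochondrially encoded genes (6.93e-06) higher, all 4 at adjusted p = 0.220 with an estimated correlation. Over the list alone 2 unfolded protein response genes, 2 vascular genes, 1 blood gene, 1 immediate early gene and 4 activated-microglia genes were lower. Ribosomal protein genes were higher (0.00159, adjusted p = 0.597 with an estimated correlation). Vascular (0.0116, adjusted p = 0.373 with an estimated correlation), blood (0.0169, the same adjusted p with an estimated correlation), neuroblast (0.0272, adjusted p = 0.652 with an estimated correlation) and myelinating oligodendrocyte markers (0.0323, adjusted p = 0.771 with an estimated correlation) were lower. Without title series in the model the ribosomal list was lower (camera adjusted p = 1.52e-07), and the mitochondrial (0.391), vascular (0.497) and neuroblast (0.0826) lists were not called. Newly called without title series were upper-layer (2.21e-04), potassium channel (0.00136), presynaptic (0.00494), axon guidance (0.00807) and postsynaptic (0.0149) lists, higher, and respiratory-chain (7.19e-05), interferon (0.0211) and cholesterol (0.0222) lists, lower. With RLE size factors astrocytes were called higher and interferon response lower (both 0.0461).

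The transgene effect differed between the ages for 56 genes, and the 5 of smallest p were Tmem252, Depp1, Nfkbia, Akap12 and the zinc-finger gene Zfp189. Tmem252 had log2 fold changes of -0.17 ± 0.26, -3.22 ± 0.30, 0.82 ± 0.32 and -0.48 ± 0.44 at 2, 6, 10 and 22 weeks. Depp1 had -0.22 ± 0.28, -3.77 ± 0.35, 0.22 ± 0.39 and 0.38 ± 0.59, and Nfkbia -0.030 ± 0.11, -1.11 ± 0.12, 0.059 ± 0.12 and -0.52 ± 0.17. The adjusted p of the test of equal effects was 9.6e-09 for Tmem252, 6.71e-08 for Depp1 and 3.87e-06 for Nfkbia (edgeR quasi-likelihood test, Benjamini-Hochberg). Among 2, 10 and 22 weeks alone, chosen after the data had been seen, 1 gene differed.

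From 2 to 6 weeks the lists of glucocorticoid response, potassium channels, myelin, MHC class I and interferon response rose in controls and those of immature neurons and proliferation fell. Only the glucocorticoid list kept its call (adjusted p = 0.0165 with an estimated correlation). The others lost it, at adjusted p = 0.425 with an estimated correlation for potassium channels, 0.567 for myelin, 0.189 for interferon response, 0.161 for MHC class I and immature neurons and 0.205 for proliferation. The largest rises were in the lipid-droplet gene Plin4 (4.94 ± 0.44), Igfn1 (4.08 ± 0.29), the astrocyte enzyme Etnppl (3.83 ± 0.39) and the kinase Plk5 (3.70 ± 0.25), besides the X-inactivation gene Xist (3.996 ± 1.02). At the transgenic level Xist had -0.645. Xist was 6.564 CPM in control_6wk replicate 5 and at most 0.02135 CPM in the other 4 D controls, all males, and its value also depends on a sex term fitted from 4 females, none of them at 6 weeks. The smallest p belonged to the Polycomb gene Cbx7 (2.41 ± 0.10, 3.81 ± 0.476 CPM, n = 7, to 20.4 ± 2.05 CPM, n = 9). Falls were led by the apelin receptor Aplnr (-4.23 ± 0.44), the neural progenitor factor Eomes (-3.61 ± 1.23), the imprinted gene Mkrn3 (-3.33 ± 0.40), the irritant-sensing channel Trpa1 (-3.28 ± 0.51) and Cd24a (-3.19 ± 0.41). Of 13 immature-neuron genes 12 fell, among them doublecortin Dcx (-2.26 ± 0.27, 124 ± 23.01 to 26.9 ± 7.94 CPM), Stmn2 (-1.09 ± 0.12) and Gap43 (-0.998 ± 0.12), and 10 of 14 proliferation genes fell, including cyclin Ccna2 (-2.09 ± 0.29). Kcnh2 itself rose (0.64 ± 0.12), and 14 of 22 voltage-gated potassium channel genes rose and 2 fell, with 1.49 ± 0.16 for Kcnh4 and 0.71 ± 0.11 for Kcna1.

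Myelin genes rose in 11 of 18 members and fell in 1, with 3.28 ± 0.26 for the nodal link protein Hapln2 and 1.62 ± 0.26 for Opalin, while 8 of 13 oligodendrocyte precursor genes fell (adjusted p = 0.189 with an estimated correlation), with -1.54 ± 0.17 for Gpr17 and -1.27 ± 0.12 for versican. The perineuronal-net genes moved apart, Hapln4 at 3.03 ± 0.20 and Hapln1 at -1.50 ± 0.12, and the interneuron gene Pvalb rose (2.16 ± 0.28) while Reln fell (-1.21 ± 0.16). MHC class I genes rose in 7 of 10, with 2.15 ± 0.13 for H2-T23, and interferon-response genes in 12 of 16, with 2.24 ± 0.27 for Irf7. Complement components rose in 7 of 15 and fell in 1 (8 and 1 over the list alone), with 0.71 ± 0.079 for C1qa, 0.74 ± 0.13 for C1qb, 0.49 ± 0.16 for C1qc and 1.16 ± 0.28 for C1ra, but as a list did not pass (0.0637, and 0.0345 without title series). Enzymes of cholesterol synthesis fell in 13 of 15 (adjusted p = 0.161 with an estimated correlation), with -0.94 ± 0.078 for Hmgcs1 and -0.91 ± 0.083 for Sqle. All 13 glucocorticoid-response genes rose, with 1.23 ± 0.14 for Sgk1 and 1.44 ± 0.14 for Zbtb16, and Lcn2 rose (4.65 ± 0.87), with -0.071 at the transgenic level. The 6-week side of this contrast is the fitted level of the D controls, in which Sgk1, Depp1 and Tmem252 stood above the other 6-week libraries.

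In all 8495 genes changed, 4062 up and 4433 down, 1708 of them more than 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.66e-29 for Cbx7 and 3.90e-10 for Dcx). At the preset correlation camera called glucocorticoid response (3.75e-09), immature neurons (6.58e-09), cholesterol synthesis (5.81e-07), MHC class I (2.11e-04), proliferation (1.62e-05), oligodendrocyte precursors (2.99e-05), interferon response (4.40e-05), myelinating oligodendrocytes (4.88e-04) and potassium channels (8.01e-04). It also called circadian genes (1.95e-04, higher, 12 of 14 rose, adjusted p = 0.189 with an estimated correlation) and olfactory neuroblasts (0.0170, lower, adjusted p = 0.712 with an estimated correlation). It called heat shock (0.0233, higher, adjusted p = 0.403 with an estimated correlation) and immediate early genes (0.00551, higher, adjusted p = 0.473 with an estimated correlation). The same held for axon guidance (0.00412, lower, 12 of 26 fell) and the unfolded protein response (0.00792, higher), both at adjusted p = 0.425 with an estimated correlation. Adjusted over the list alone, the counts were 13 of the glucocorticoid genes, 12 immature-neuron, 14 cholesterol, 7 MHC class I, 11 proliferation, 8 precursor, 13 interferon, 12 circadian, 11 myelin, 16 potassium channel and 12 axon guidance genes in the direction of their list. All 2-week libraries belong to the P14 series, so age and title series cannot be told apart in this contrast, and without title series the unfolded protein list was not called (0.0556). With a 6-week genotype effect of its own in each series, a fit chosen after the data had been seen, 8367 genes were called and all 15 lists kept their calls. That fit still takes its 6-week level from the D controls, so it does not test how far these calls rest on them.

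From 6 to 10 weeks, at the fitted control level of the D series, the lists of glucocorticoid response, unfolded protein response and heat shock fell and mitochondrially encoded genes rose. These calls were lost at adjusted p = 0.0721, 0.349, 0.349 and 0.520 with an estimated correlation, in this order. Depp1 (-3.79 ± 0.38), Maff (-3.77 ± 0.38), Tmem252 (-3.099 ± 0.33) and Tcim (-2.75 ± 0.32) had the largest falls apart from Xist (-3.86 ± 1.31), which was high in 1 D control of 6 weeks, control_6wk replicate 5 (6.564 CPM), and had 3.875 at the transgenic level. Of the 13 glucocorticoid-response genes 8 fell, among them Fkbp5 (-1.002 ± 0.10), Tsc22d3 (-1.06 ± 0.12) and Sgk1 (-1.21 ± 0.15). In the unfolded protein response 8 of 14 genes fell and 1 rose, with -0.54 ± 0.081 for Xbp1 and -0.57 ± 0.097 for Hspa5, and 6 of 11 heat-shock genes fell and 1 rose, with -0.44 ± 0.087 for Dnajb1. The mitochondrial rRNA mt-Rnr1 (2.56 ± 0.30), the mitochondrial tRNA synthetase gene Lars2 (2.33 ± 0.87, and -1.11 without title series in the model), Rps16 (2.30 ± 0.23), the cytokine Tnfsf10 (1.98 ± 0.27) and Clec2d (1.87 ± 0.22) were among the largest rises. Of the mitochondrially encoded genes 7 of 13 rose, with 1.21 ± 0.18 for mt-Cytb. Microglial markers rose in 5 of 20 and fell in 2 (adjusted p = 0.957 with an estimated correlation), with 0.81 ± 0.12 for Laptm5 and 1.29 ± 0.21 for Sall1. Of 18 immediate early genes 4 rose, Npas4 (1.34 ± 0.20) and Arc (0.88 ± 0.24) among them, and 1 fell (5 higher and 4 lower over the list alone), and the list was not called (0.354, adjusted p = 0.957 with an estimated correlation).

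In all 1902 genes rose and 2100 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 8.43e-11 for Depp1 and 2.06e-06 for mt-Cytb). Camera called glucocorticoid response (7.52e-07; 8 lower over the list alone), mitochondrially encoded genes (1.18e-05; 8 higher), the unfolded protein response (4.34e-05; 8 lower) and heat shock (0.00280; 7 lower). It also called the nuclear respiratory chain (0.0151, lower; 5 of 24 fell, 6 over the list alone) and microglia (0.0244; 8 higher and 2 lower over the list alone), both lost at adjusted p = 0.957 with an estimated correlation. The contrast shares its 5 D controls of 6 weeks with the 2-to-6-week and 6-week transgene contrasts, so genes they have in common are not independent findings. At the transgenic level Depp1 (0.19) and Sgk1 (0.071) did not pass and Tmem252 rose (0.94), in log2. With a 6-week genotype effect of its own in each series, a fit chosen after the data had been seen, 3829 genes were called and all 6 lists kept their calls. That fit still takes its 6-week level from the 5 D controls, so it does not test how far these calls rest on them. Without title series the microglial list was not called (0.151), and meningeal (0.00840), cholesterol (0.0190) and precursor (0.0304) lists were called lower and the presynaptic list higher (0.0114). Mitochondrial reads made up 5.46% to 8.94% of counts in the 6-week D controls and 17.3% to 21.5% in the 10-week D controls. Among 22-week D transgenics the share was 6.096% and 5.229% in replicates 4 and 5, and 20.846% to 22.004% in replicates 1 to 3. It thus varied within D at a single age. Other differences between the 6-week and 10-week D libraries are not told apart from age in this contrast.

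From 6 to 22 weeks, at the fitted control level of the CTX series, the ribosomal protein list rose and the presynaptic, microglial, oligodendrocyte precursor and myelin lists fell. These calls were lost at adjusted p = 0.400, 0.513, 0.513, 0.425 and 0.659 with an estimated correlation, in this order. Ribosomal protein genes rose in 8 of 30 (20 over the list alone), with 0.56 ± 0.12 for Rps14 and 0.38 ± 0.097 for Rps23. Presynaptic genes fell in 4 of 19 (6 over the list alone), namely Stx1a (-0.53 ± 0.098), Rab3a (-0.39 ± 0.080), Syp (-0.42 ± 0.098) and Unc13a (-0.38 ± 0.11). The G protein regulator Rgs4 (-0.76 ± 0.11) and the interneuron peptides Npy (-0.61 ± 0.13) and Cck (-0.54 ± 0.11) fell. Microglial markers fell in 4 of 20 (7 lower and 2 higher over the list alone), with -0.44 ± 0.11 for Fcrls and -0.44 ± 0.11 for Csf1r. Precursor genes fell in 3 of 13 (6 over the list alone), with -0.77 ± 0.17 for Neu4 and -0.96 ± 0.23 for Gpr17, and myelin genes fell in 3 of 18 (5 lower and 1 higher over the list alone), with -1.09 ± 0.29 for Cldn11. The largest falls were in the interferon-induced Gbp4 (-2.09 ± 0.55), the lysosomal GTPase gene Rab7b (-1.97 ± 0.30), Rassf10 (-1.81 ± 0.39), the matricellular gene Ccn1 (-1.55 ± 0.38) and Edn1 (-1.50 ± 0.39), and the endothelial adhesion gene Pecam1 fell (-0.55 ± 0.11). Rises of 4.66 ± 1.18 in the dynein gene Dnah11 and 2.34 ± 0.58 in the mitochondrial tRNA mt-Tw were among the largest. The fitted 6-week level also draws on the CTX transgenics, through a genotype effect shared with the D series. In a fit with a 6-week genotype effect of its own in each series, chosen after the data had been seen, 10 genes of this paragraph did not pass. They were Ccn1 (-0.346), Edn1 (-0.861), Dnah11 (3.863), mt-Tw (1.89), Csf1r (-0.412), Cldn11 (-1.141), Neu4 (-0.678), Cck (-0.431), Syp (-0.352) and Unc13a (-0.376), in log2 fold change. Rises of 10.55 ± 1.72 in Gh, 9.51 ± 1.83 in Prl and 5.25 ± 0.83 in Pomc rested on control_22wk replicate 1.

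In all 416 genes rose and 377 fell between the fitted CTX control levels, with 2 CTX controls at 6 weeks and 4 at 22 weeks and the spread taken from all 69 libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.18e-05 for Rgs4 and 0.00303 for Rps14). With a 6-week genotype effect of its own in each series 255 genes were called, 238 of them among the 793, and 21 lists, among them all 13 called in the main fit. The glucocorticoid (0.00511) and immediate early (0.0272) lists were among the other 8, both higher. Camera called ribosomal protein genes (2.33e-15), oligodendrocyte precursors (5.24e-05), presynaptic genes (3.31e-04), myelinating oligodendrocytes (0.00295) and microglia (0.00520). It called endothelial cells and pericytes (5.24e-05, lower, adjusted p = 0.400 with an estimated correlation). It called mitochondrially encoded genes (2.64e-04, higher), blood (0.00792, higher) and cortical excitatory markers (0.0240, lower), these 3 lost at adjusted p = 0.513 with an estimated correlation. Proliferation (0.0451, lower) was lost at adjusted p = 0.659 with an estimated correlation, neuroblasts (0.00382, higher) and axon guidance (0.0325, lower) at 0.631 as adjusted p with an estimated correlation, and cholesterol synthesis (0.00839, lower) at 0.531 likewise. Over the list alone 3 vascular genes were lower, and 1 mitochondrial, 4 blood and 4 neuroblast genes higher. Without control_6wk replicate 4, 1 of the 2 CTX controls of 6 weeks, 282 genes were called, and without title series in the model 7102 were called, while the microglial (0.222), myelin (0.774), blood (0.108), cortical excitatory (0.222), proliferation (0.619) and cholesterol (0.622) lists were not. Without title series the respiratory-chain list was called higher (3.28e-05), and the potassium channel (3.16e-04), upper-layer (6.67e-04) and postsynaptic (0.00636) lists lower.

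Some lists were called in none of the 8 contrasts of the main fit. The smallest camera adjusted p was 0.0696 for deep-layer markers (1 of 13 rose and 7 fell from 2 to 6 weeks), 0.0756 for interneurons (transgene average, median -0.044), 0.0796 for GABA receptors and 0.0885 for perineuronal nets (both from 6 to 22 weeks). With a 6-week genotype effect of its own in each series the last 2 lists were called, lower, at 0.0317 and 0.0195. Deep-layer markers were called at 10 weeks without title series (higher, 0.0134) and dopamine signalling at 6 weeks with both the D controls and title series left out (lower, 0.0311). In the main fit it was 0.101 for dopamine signalling (transgene at 10 weeks), 0.245 for 5 genes at the insertion site of a widely used forebrain tetracycline transactivator driver (transgene at 22 weeks) and 0.271 for choroid plexus (6 to 22 weeks). Of those 5 genes none passed over all genes with the transgene at any age, and at 22 weeks 3 were lower when adjusted over the list alone. Their values at 22 weeks were -2.26 ± 0.97 for Vipr2, -0.40 ± 0.14 for Wdr60, 0.31 ± 0.15 for Ncapg2, -0.23 ± 0.10 for Ptprn2 and 0.003 ± 0.075 for Esyt2. Which driver line these animals carried is not given in the sources used here.

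**Figure D4:**
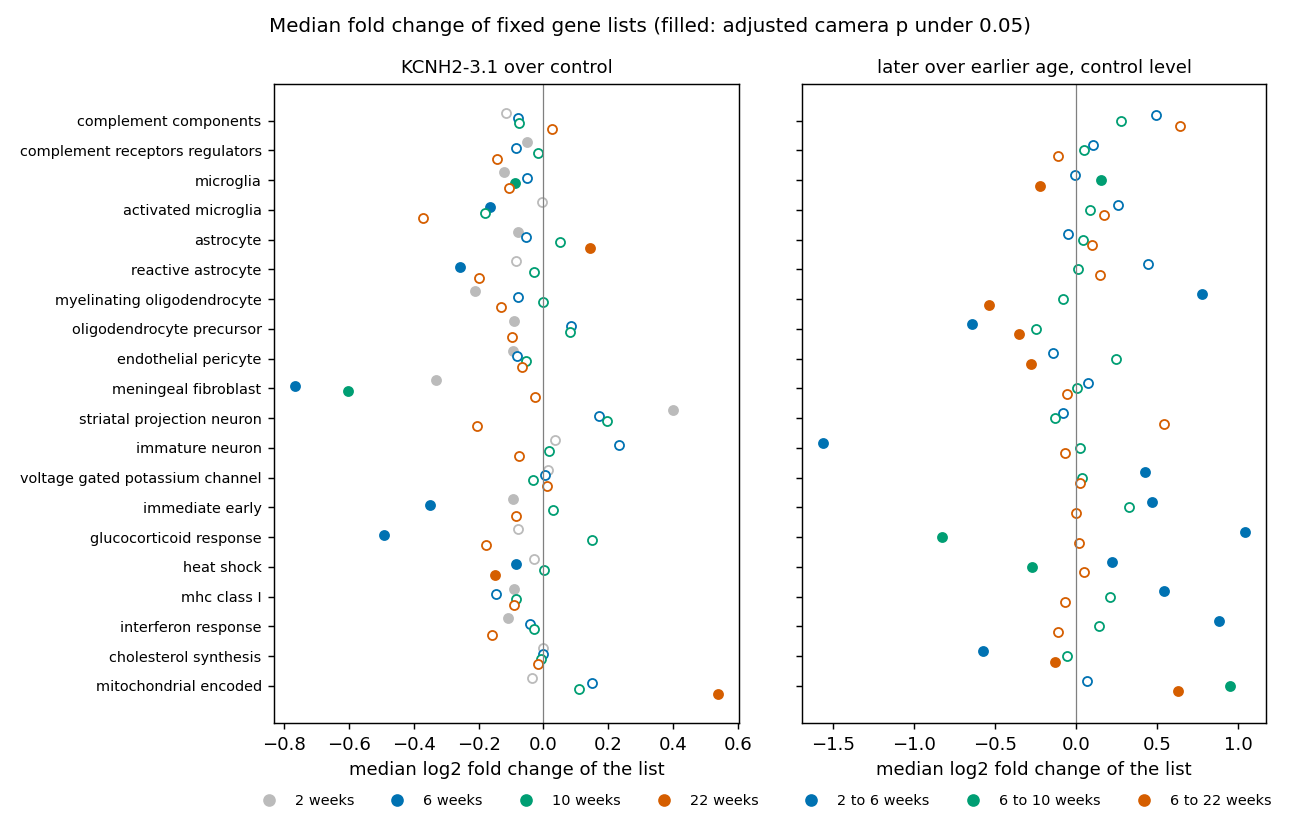
Median log2 fold change of a part of the 39 gene lists on the horizontal axis, with filled marks for a camera adjusted p under 0.05. The transgene contrasts at 4 ages are in 1 panel and the age contrasts at the control level in the other. Ribosomal protein, respiratory-chain, neuroblast, blood, unfolded protein and upper-layer lists are among those not shown. Microglial markers had a median of -0.12 at 2 weeks and glucocorticoid-response genes one of -0.49 at 6 weeks with the transgene.

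Cwc22, named above among the 10-week genes, varied widely between libraries, and was examined in each library after its values had been seen. It ran from 3.72 to 6.6 log2 CPM in the 11 transgenics of 10 weeks and from 6.2 to 7.53 in the 7 D controls, and over all libraries no value lay between 4.52 and 5.65. Below that gap lay 17 of the 39 transgenic libraries and 1 of the 30 controls. The fitted log2 fold changes of Cwc22 were -0.89 ± 0.40 at 2 weeks, -0.93 ± 0.42 at 6 weeks, -1.75 ± 0.40 at 10 weeks and 0.28 ± 0.60 at 22 weeks, and none passed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.162 at 10 weeks). Cwc22 lies on chromosome 2 from 77881159 to 77946375 (GRCm38).

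**Figure D5:**
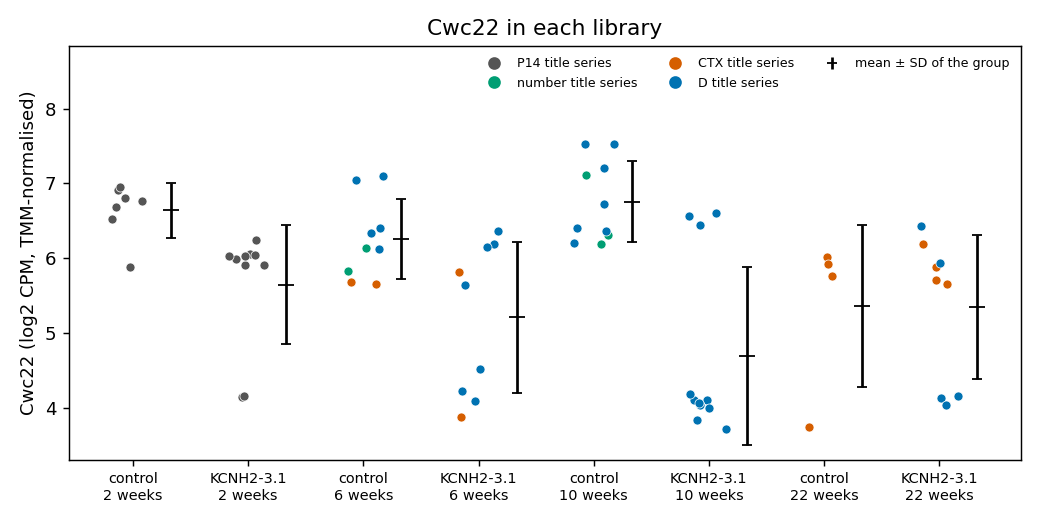
Cwc22 in log2 CPM on the vertical axis for each of the 69 libraries, grouped by age and genotype, with the mark giving the title series. The 18 libraries below the gap lie at 4.52 or less, and the other 51 at 5.65 or more.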

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

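Samples far from the rest of their group were sought in 16 measures over 7 groups of 4 to 10 libraries. Of these 112 tests 13 had a gap beyond the 95% limit, and chance alone gives about 1 in 20. Gh, Ttr and Depp1 were added as measures after their values had been seen. Pituitary Gh stood at 12.88 log2 CPM in control_22wk replicate 1 against -0.47 in the next library, and at -1.73 in control_2wk replicate 4 against -3.76. Ttr, a choroid plexus gene, stood at 10.62 in KCNH2-3.1_22wk replicate 3 (next 4.3) and 6.98 in KCNH2-3.1_6wk replicate 8 (next 2.31), and the choroid plexus score was 4.24 (next -0.38) and 0.76 (next -0.94) in the same 2 libraries. The striatal score was 4.16 in KCNH2-3.1_2wk replicate 2 (next 3.02) and the blood score 5.67 in control_6wk replicate 1 (next 4.62). Kcnh2 was highest in control_2wk replicate 3 (3.95 log2 CPM, next 3.5) and control_22wk replicate 1 (3.96, next 3.64) and lowest in control_10wk replicate 4 (3.61, next 4.13). Depp1 was lowest in control_10wk replicate 3 (-2.96, next -1.05), and the total count was highest in control_10wk replicate 2 (37.57 in units of 1e6 reads, next 22.89). By a test of the difference itself, the transgene effect differed between ages for 56 genes. Spike-in reads, which no comparison used, exceeded 1% of counts in 12 libraries, all of the CTX series.

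The 6-week falls, of Depp1 and Nfkbia among 133 genes, were weighed with tests chosen after the result was seen. Raised values in the 5 D controls fitted, since the median log2 difference of the 133 genes was -0.118 within CTX and -0.799 within D. A transgene effect of the same size in every series was argued against, as the lowest of the CTX library pairs was -0.235. These pairs reuse 2 libraries per genotype. The 133 genes were called in a fit that held the same D libraries, so their D median is enlarged by that choice. The gap between the series is therefore overstated, by an amount that was not tested. Low depth and rRNA-like reads of KCNH2-3.1_6wk replicate 1 were argued against, as 120 of the 133 genes stayed called without it. Of the 51 higher genes, which are not part of this pattern, 30 stayed called. Of the 133 genes 96 were lower within CTX, and 100 were lower with both the D controls and title series left out (median -0.173). Differences between series enter that last fit. The D transgenics lay at -0.267 relative to the number controls. EdgeR's quasi-likelihood test of the effect in D against that in CTX called 8 of the 133, and 66 had an unadjusted p under 0.05. With 2 CTX libraries per genotype (median -0.118), a smaller transgene effect could remain, and the source of the raised D controls was not tested.

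The 22-week falls of Gh, Prl and Pomc were weighed with 2 marker tests written before their values were seen and 2 tests chosen after. Anterior pituitary tissue in control_22wk replicate 1 fitted, as 9 of 10 detected pituitary markers, Cga and Tshb among them, were highest of the 69 libraries there (0.14 by chance). Hypothalamic tissue was argued against, with 0 of 9 detected markers highest there. A transgene effect on Gh, Prl and Pomc was argued against, since their median without that library was 1.1 against -9.66 with it. For the other 18 lower genes the median was -0.429 without it and none stayed called, which leaves a transgene effect open. Of all 21 lower genes, 11 had their highest 22-week value in control_22wk replicate 1, Gh, Prl and Pomc among them.

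Differences of 1 sign at 2, 6 and 10 weeks, none of which passed at a single age, clustered on chromosome 2 around Cwc22, Itga4 and Fam171b, and all 4 tests of this were chosen after the result was seen. Chance placement of genes that vary independently was argued against, with a permutation p of 1e-04, the smallest the 10000 permutations can give. A chromosome segment that differs between the animals fitted, as 12 of the 50 genes that follow Cwc22 most closely lay in the window (0.16 expected). The permutations moved each gene by itself, while these window genes varied together between libraries. They therefore do not exclude that such a segment fell unevenly between the genotypes by chance. Reads lost to strain variants stay open, since 5 of the 8 window genes were higher and 3 lower and the strains of the animals are not given in the sources used here. Of genes chosen at 2 and 6 weeks, 10 of 10 in the window and 10 of 12 elsewhere kept their sign at 10 weeks (Fisher exact p = 0.48). Signs thus do not set the window apart, but left little room to do so. Of the same genes 8 in the window and 3 elsewhere also had an unadjusted p under 0.05 at 10 weeks by edgeR's quasi-likelihood test. The window was placed using those values, so this count does not test it. No biological explanation was tested.

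Other splits of the same libraries, planned before the data were examined, were run for each count of genes and include the real split. At 2 and 10 weeks the real count was 0, which every split reaches (100 of 100 at both ages, highest other 1 and 4), so these splits decide nothing. At 6 weeks 2 of 100 called as many as 184 (highest other 517), for the average 2 of 100 as many as 24 (highest other 306), and for the difference between ages 3 of 100 as many as 56 (highest other 137). At 22 weeks 12 of 35 called as many as 28 (highest other 1425), so the 22-week count is not told apart from other groupings. Any gene at all was called in 68 of the other splits at 6 weeks and 34 at 22 weeks. For the average 9 did so, for the difference between ages 96, and at 2 and 10 weeks 4 and 3. Splits calling more than the real count, up to 517, 306 and 1425 genes, show that groupings other than genotype can give such counts, and the cause was not tested. For age, 1 of 30 splits called as many as 8495 from 2 to 6 weeks (highest other 3401), 1 of 30 as many as 4002 from 6 to 10 weeks (highest other 260) and 1 of 30 as many as 793 from 6 to 22 weeks (highest other 277).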

How the results depend on the processing

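Counts moved with the processing as follows, and beyond the design limit given for title series the cause was not tested. With no low-count filter 2 genes were called at 2 weeks, 8 at 22 weeks and 12 in the average. With DESeq2 1 was called at 2 weeks, 332 at 6 weeks, 4 at 10 weeks, 62 in the average and 135 for the difference between ages. Without title series 120 were called at 6 weeks, 1 at 10 weeks and 733 at 22 weeks. For the difference between ages 21 were then called, and 7102 from 6 to 22 weeks. At 22 weeks that fit sets 5 D and 4 CTX transgenics against 4 CTX controls, so differences between title series enter the count. With 2 surrogate variables 1 was called at 2 weeks, 221 at 22 weeks, 79 in the average and 90 for the difference between ages. With each age fitted alone 70 were called at 6 weeks, 1 at 10 weeks and 0 at 22 weeks. With RLE size factors 188 were called at 6 weeks and 30 at 22 weeks, within 1.5 times of the main counts.

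Of the alternatives chosen after the data had been seen, the D series alone gave 365 genes at 6 weeks and the CTX series alone 0. Leaving out both the D controls and title series gave 15. That fit sets 7 D and 2 CTX transgenics against 2 number and 2 CTX controls, so differences between series enter it. The average over 2, 10 and 22 weeks gave 0 and the difference among them 1. With a 6-week genotype effect of its own in each series, 255 genes and 21 lists were called from 6 to 22 weeks, against 793 and 13. That fit removes from the 6-week control levels what they draw from the transgenics. With an estimated correlation the lists called were 1 of 13 at 2 weeks, 4 of 7 at 6 weeks, 0 of 4 at 10 weeks, 0 of 8 at 22 weeks, 4 of 17 in the average, 1 of 15 from 2 to 6 weeks, 0 of 6 from 6 to 10 weeks and 0 of 13 from 6 to 22 weeks. With both the 6-week D controls and title series left out 17 lists were called.

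Leaving out each library in turn gave 0 to 1 genes at 2 weeks, 106 to 275 at 6 weeks, 0 to 4 at 10 weeks, 1 to 121 at 22 weeks, 6 to 55 in the average, 7726 to 8844 from 2 to 6 weeks, 3125 to 4485 from 6 to 10 weeks and 282 to 1070 from 6 to 22 weeks. Without control_22wk replicate 1, 7 lists were called at 22 weeks.

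Values of genes reported here that passed in the main fit and turned direction, in log2 fold change, were these, and the cause was not tested. In the CTX series alone at 6 weeks they were Mex3b -0.017, Slc40a1 -0.146, Maff 0.567, Atf3 0.810, Apold1 0.011, Akap12 0.093, P2ry13 -0.338, Lcn2 1.421, Fosl2 0.074, Nr4a1 0.058, Dusp1 0.466, Errfi1 0.084 and Dnajb1 0.101. With both the D controls and title series left out they were Rassf9 -0.032, Mex3b -0.089, Slc40a1 -0.153, Slc30a1 -0.055, Cmtr2 -0.066, Maff 0.305, Atf3 0.384, Apold1 0.287, Akap12 0.078, Edn1 0.125, P2ry13 -0.043, Hspb1 0.063, Arntl 0.120 and Fkbp5 0.398. Without title series they were Dio2 -0.083 at 22 weeks and Lars2 -1.109 from 6 to 10 weeks. Over 2, 10 and 22 weeks Tmem252 averaged 0.056. At the transgenic level they were Xist -0.645, H2-Ab1 -0.237 and Lcn2 -0.071 from 2 to 6 weeks, and Xist 3.875, Depp1 0.193, Tmem252 0.936, P2ry13 -0.069, Lcn2 2.193, Sgk1 0.071 and Rpl18 0.022 from 6 to 10 weeks. With the transgene Kcnh2 passed in none of these fits, and its value turned to 0.428 at 22 weeks without title series and to 0.006 at 6 weeks in the CTX series alone.

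Of 387 values of named genes, 383 kept direction and call with RLE size factors, 376 with DESeq2, 373 with males only and 310 without title series, and of 375 with a filter of 1 CPM, 371 did. For age contrasts 295 of 323 did with a 6-week genotype effect of its own in each series and 235 of 276 at the transgenic level. For transgene contrasts 45 of 64 did with no low-count filter, 56 of 64 with 2 surrogate variables and 17 of 48 with each age fitted alone. At 6 weeks 35 of 36 did in the D series alone, 0 of 36 in the CTX series alone and 0 of 36 with both the D controls and title series left out. In the average over 2, 10 and 22 weeks 0 of 15 did. Of simulated changes of 0.5 in log2, 73.7% were recovered at 2 weeks, 37.5% at 6, 32.1% at 10 and 27.8% at 22 weeks, and the cause was not tested. These shares rest on 19, 16, 28 and 18 genes, in this order, and the gene sets differed between the ages. No paired analysis was possible because replicate numbers are only the order of the samples and no label links a control to a transgenic animal.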

Other observations

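Genes around Cwc22 on chromosome 2 had transgene values of 1 sign at 2, 6 and 10 weeks, each at an unadjusted p under 0.05, and were singled out after their values had been seen. None passed over all genes at any single age. The integrin subunit gene Itga4 had log2 fold changes of 0.36 ± 0.12, 0.33 ± 0.13 and 0.46 ± 0.14, the integrin gene Itgav 0.32 ± 0.14, 0.41 ± 0.14 and 0.31 ± 0.14, the ceramide kinase-like gene Cerkl -0.75 ± 0.25, -0.56 ± 0.27 and -0.70 ± 0.28, and the C1 inhibitor Serping1 -0.55 ± 0.27, -0.91 ± 0.30 and -0.68 ± 0.29. Of 11 such genes in the genome 8 lay in the 10 Mb window, and 4 of the 8 kept their sign at 22 weeks. Serping1 belongs to the complement regulators and lies in this window. The C1 inhibitor values are therefore not separated here from those of its neighbours.

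The pituitary hormone subunits Cga and Tshb reached 238 and 53.1 counts per 1e6 reads of plain total count in control_22wk replicate 1. No other library exceeded 0.238 for Cga or 0.0954 for Tshb on that scale. Neither gene passed the count filter. The first 2 principal components held 23.8% and 9.9% of the variance.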
